A study of Mus musculus with 6 samples.

How the data were processed

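RNA of mouse peritoneal exudate cells, which the labels also call peritoneal macrophages, was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of total RNA for Affymetrix arrays, per the labels' protocols. All samples carry the strain label C57BL/6. The deposited series table holds linear signal intensities for 12488 probe sets on 6 arrays, made with MAS5 per the submitters' processing notes. Its version, scaling target and any detection calls are not given in the sources used here. The values were taken as linear intensity from their range, 0.1 to 39853, and each array's mean without the lowest and highest 2% of probe sets lay within 500.3 to 500.4, so the deposited signals were already on 1 scale. Array files from the scanner were not used here.

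Groups were taken from the sample labels: 3 genotypes (WT, KO and KI) in 2 states (untreated, and LPS with interferon-γ), with 1 array in each group. The labels number no replicates, so arrays could not be paired by replicate, and they do not say whether an array stands for 1 animal or a pool. Intensities were rescaled to the mean of the arrays' trimmed means, given a floor at the 40th percentile of all scaled values (a signal of 97.99) and converted to log2. A change that starts or ends at the floor is understated, and a fold against a signal under the floor is given as "at least", computed against the floor. The 66 Affymetrix control probe sets were left out, and of the remaining 12422 the 9344 above the floor on at least 1 array were used. Gene names came from the platform annotation of the probe sets: of 12422, 10833 have 1 symbol, 396 several and 1193 none, and none was named from a probe set with several. Symbols were checked through gene identifiers against the RefSeq genes of assembly GRCm38.p6, where 10839 probe sets matched and 0 symbols changed; that table was used for names and for which genes neighbour each other. Each of 6767 named genes is represented by its probe set with the highest mean log2 intensity, and its other probe sets entered only 1 of the alternatives.

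Computations ran in R 4.3.3 with limma 3.58.1. The effect of stimulation was fitted over all 6 arrays with genotype as a block, and genotype effects in the same additive fit, with 2 residual degrees of freedom, eBayes with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. With no replicates, the error of this fit holds the variation of the response between genotypes along with noise, so its p-values do not measure the spread between animals or cultures. An exact sign-flip test of 3 pairs cannot go below a p of 0.25 and was not used. Induction within a genotype, differences in induction and differences per state have no residual degrees of freedom; they are given by size, at least 1 on the log2 scale, without a p-value. A fixed set of 37 gene lists, 10 of them markers of cell types that an exudate could hold, was tested with camera (preset correlation 0.01, two-sided), again with the correlation estimated, and with fry; 35 lists had the 5 measured members needed. Differences between genotypes in induction were described by the percentile of a list's median among 10000 random lists of the same size matched on mean log2 intensity in 20 bins. The same percentiles within a genotype and within a state were added after the data had been examined. The central range of random lists runs from percentile 2.5 to 97.5.

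The groups, tests, lists, rule for named genes and nearly all alternative settings were chosen before the data were examined. The genes named are Cebpb, Cebpa, Cebpd, Il6, Csf3, Ptges, Ptgs2, Nos2, Il12b, Tnf, Il1b, Lcn2, Saa3 and Arg1 in any comparison; for stimulation the 12 largest rises and 12 largest falls among genes past the test and moved by at least 1 in all 3 genotypes; for induction and state differences the 12 largest in each direction for KO against WT and the 8 largest for the other contrasts, among probe sets whose highest array reached the 75th percentile (a signal of 531.8); and up to 4 members of each list described. Genes induced less without NF-IL6 were those induced by at least 2 on the log2 scale in WT and by at least 1.5 less in KO, for which the KI induction was placed on the line from KO to WT.

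The code was tested on simulated data. With 200 of 9344 probe sets changed in each of 10 simulations, the stimulation test recovered 35.2% of changes of 1 on the log2 scale, 77.8% of 2, 80.6% of 3 and 80.0% of 4, with 3.39% of calls false. The KO against WT test recovered 20.2%, 62.4%, 69.4% and 71.0% of the same sizes, with 3.04% false. For both tests the noise was drawn with the moderated variances of the fit. Each simulated change was also the same in every genotype or state, so these shares need not hold for the real arrays. Over 6767 genes a shifted list was called for stimulation in 10 of 10 simulations and 0 of 340 unshifted ones were, and 6 of 100 random lists fell outside the central range. The simulated genes were drawn independently and the 100 random lists held genes drawn at random. Neither the 0 of 340 nor the 6 of 100 is therefore a false call rate for lists of correlated genes. Alternatives to the scaling, floor, filter, eBayes prior, block, size rule, probe sets of a gene and list test were computed, as were fits without each array and without each genotype; the fit of gene lists without each genotype was chosen after seeing the data.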

Results

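The data were 6 single-colour Affymetrix arrays hybridised with RNA from mouse peritoneal exudate cells, a preparation rich in macrophages. Cells came from wild-type mice (WT), from mice without NF-IL6 (KO) and from a knock-in line that the labels call KI(LAP) (KI). NF-IL6 is C/EBPβ, a leucine-zipper transcription factor encoded by Cebpb, and LAP is the name of its activating form. Each genotype was measured untreated and after lipopolysaccharide (LPS) with interferon-γ, a stimulus of classically activated macrophages. The labels gave 12 h of stimulation for the KO and KI cells and no time for the WT cells. There was 1 array per genotype and state, so no group had a replicate and the number of arrays limited the precision of every value below. The deposited median signal was 185 on the untreated WT array and 164 on the stimulated one, 172 and 151 on the KO arrays, and 147 and 131 on the KI arrays. The share of probe sets above the floor used here, a signal of 98.0, ran from 65.8% on the untreated WT array to 55.7% on the stimulated KI array. The median of 19 negative-control probe sets was 49.8 on the untreated WT array and between 17.8 and 34.8 on the other arrays. None of the 15 pairs of arrays held identical values.

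The targeted gene was examined first. Cebpb had a signal of 5492 in untreated and 9329 in stimulated WT cells. On the KO arrays its signal was 12.7 and 59.0, both under the floor, which put it at least 56.0-fold lower than WT before and at least 95.2-fold lower after stimulation. The KI arrays gave 2284 and 5890, which was 2.40-fold and 1.58-fold below WT in the same states. Where the probe set lies relative to the deleted or inserted part of the gene was not given in the sources used here.

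After LPS with interferon-γ, interferon-inducible genes rose most in all 3 genotypes. Ccl5, a chemokine for T cells and monocytes, rose from a signal of 74.9 to 24846 in WT, from 180 to 21963 in KO and from 35.2 to 21775 in KI cells (mean log2 change 7.57, SE 0.24, limma adjusted p = 0.000325). Cxcl9, an interferon-γ-induced chemokine, reached 12797, 13143 and 12885 in WT, KO and KI cells from signals under the floor (mean log2 change 7.04 with the floor, SE 0.13, limma adjusted p = 0.000189). Iigp1 and Gbp2b, GTPases that act against intracellular microbes, rose by 6.46 and 6.22 on the log2 scale. Fabp7, a fatty-acid-binding protein, fell from 3603 to 136 in WT, from 2143 to 62.5 in KO and from 2943 to 98.4 in KI cells (mean log2 change -4.69, SE 0.19, limma adjusted p = 0.000712). In the limma fit of stimulation with genotype as a block, 470 of 9344 probe sets rose and 562 fell, and 2542 had an unadjusted p under 0.05. Centring each array on its median turned this split to 613 and 372. Of these probe sets, 301 that rose and 235 that fell also moved by at least 1 on the log2 scale in every genotype, which made 233 and 193 named genes. The fit measured how far the response varied between the 3 genotypes, not between replicate cultures. With either untreated or stimulated array of any genotype left out, at most 15 probe sets rose past the threshold.

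Among those named genes, the largest rises after Gbp2b belonged to Acod1, the enzyme that makes itaconate (6.16), Ifit2 and Ifit1, interferon-induced proteins that bind viral RNA (6.12 and 5.87), Ptgs2, the inducible cyclooxygenase (5.89), Gm9706 (5.85), Isg15, a ubiquitin-like modifier (5.78), Gbp2 (5.78) and Il12b, the p40 subunit of interleukin 12 (5.60), all as mean log2 change with limma adjusted p from 0.000189 to 0.00177. The largest falls after Fabp7 were those of Cd93 (-3.81), Hal, the histidine-degrading enzyme (-3.65), Emp1 (-3.61), the integrin Itgb5 (-3.59), the diacylglycerol lipase Daglb (-3.57), Adssl1 (-3.50), Sesn1 (-3.26), the transcription factor Lyl1 (-3.19), Tmem37 (-3.11), the sialyltransferase St8sia4 (-3.03) and Gdf3 (-2.91), with limma adjusted p from 0.00122 to 0.00869. Members of the interferon lists moved together. All 9 measured interferon-inducible GTPases rose, with a median log2 change of 4.67 (camera adjusted p = 4.92e-16), and so did 17 of 21 type I interferon response genes (median 3.35, camera adjusted p = 3.79e-20), both with adjusted p = 0.243 with an estimated correlation. Adjusted over the list alone, the counts were 9 and 18, with 1 interferon response gene lower. Irf7 and Irf1, transcription factors of the interferon response, rose by 4.12 and 3.35, and Mx1 and Rsad2, antiviral effectors, by 5.13 and 4.76.

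Genes of NF-κB signalling and its feedback rose in 17 of 23 cases (median 1.87, camera adjusted p = 3.67e-17, adjusted p = 0.302 with an estimated correlation) and in 19 when adjusted over the list alone. Cd40, a costimulatory receptor, rose by 5.32, Traf1 by 4.40, Socs1, an inhibitor of cytokine signalling, by 4.29, and Socs3 by 3.88. Of 15 inflammatory cytokines, 8 rose (median 1.44, camera adjusted p = 2.17e-10, adjusted p = 0.339 with an estimated correlation), or 12 adjusted over the list alone. Il1b, Tnf and Il6 rose by 5.26, 5.18 and 3.57 on the log2 scale, with limma adjusted p of 0.00213, 0.00202 and 0.00751. Csf3, the granulocyte growth factor, did not pass the test (0.87, SE 0.29, limma adjusted p = 0.137). Among 19 chemokines, 9 rose and 2 fell (median 1.41, camera adjusted p = 1.1e-06, adjusted p = 0.302 with an estimated correlation), with 11 and 3 adjusted over the list alone. Cxcl10 and Ccl7 rose by 5.27 and 4.43, and Cxcl14 fell by 2.73.

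Antigen presentation and protein breakdown rose as well. Of 12 genes of the MHC class I pathway, 7 rose (median 1.995, camera adjusted p = 8.11e-10, adjusted p = 0.302 with an estimated correlation), and 9 adjusted over the list alone. Tap1, the peptide transporter, rose by 3.76, and the immunoproteasome subunits Psmb9 and Psmb8 by 2.35 and 2.06. Of 29 core proteasome genes, 10 rose (median 0.50, camera adjusted p = 8.11e-10, adjusted p = 0.339 with an estimated correlation), and 17 adjusted over the list alone, Psma5 by 1.54. In the MHC class II pathway, 3 of 11 rose (median 0.50, camera adjusted p = 0.0019, adjusted p = 0.302 with an estimated correlation), and 6 adjusted over the list alone, H2-DMb1 by 1.76. Among 18 antimicrobial effectors, 5 rose (median 0.44, camera adjusted p = 0.0019, adjusted p = 0.302 with an estimated correlation), and over the list alone 5 were higher and 3 lower. Nos2, the inducible nitric oxide synthase, rose by 4.54 (SE 0.22, limma adjusted p = 0.00122). Apoptosis and survival genes rose in 6 of 18 cases (median 0.24, camera adjusted p = 0.00162, adjusted p = 0.302 with an estimated correlation), adjusted over the list alone in 7 with 1 lower, led by the inflammatory caspase Casp4 (2.46).

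Metabolic genes moved both ways. Of 13 glycolysis genes, 5 rose (median 0.50, camera adjusted p = 3.78e-05, adjusted p = 0.397 with an estimated correlation), and 7 adjusted over the list alone. Pfkp, a phosphofructokinase, rose by 2.31 and Slc2a1, the glucose transporter, by 1.87. Of 18 oxidative stress genes, 2 rose (median 0.30, camera adjusted p = 0.00299, adjusted p = 0.5 with an estimated correlation), and 4 adjusted over the list alone, led by Sod2, the mitochondrial superoxide dismutase (2.42). Genes of lipid handling fell in 7 of 18 cases and rose in 1 (median -0.72, camera adjusted p = 0.00298, adjusted p = 0.302 with an estimated correlation). Adjusted over the list alone, 10 fell and 1 rose. Pparg, a lipid-sensing nuclear receptor, fell by 2.27, Cd36, a scavenger receptor, by 1.75, and Nr1h3 rose by 1.52. Of 13 cholesterol synthesis genes, 3 fell (median -0.64, camera adjusted p = 0.0061, adjusted p = 0.538 with an estimated correlation), also 3 adjusted over the list alone. Of 20 ribosomal protein genes, 3 fell (median -0.40, camera adjusted p = 0.0183, adjusted p = 0.546 with an estimated correlation), and 10 adjusted over the list alone. The camera call for cholesterol synthesis ended without both KI arrays (adjusted p = 0.0603, chosen after seeing the data) and with a floor at the 60th percentile (adjusted p = 0.0507), and that for ribosomal proteins with a floor at the 20th percentile (adjusted p = 0.0807). C/EBPβ target genes taken from the literature rose in 8 of 20 cases and fell in 1 (median 0.73, camera adjusted p = 0.000281, adjusted p = 0.339 with an estimated correlation), with 11 and 4 adjusted over the list alone. Il1rn, the interleukin 1 receptor antagonist, rose by 2.11, while Saa3, an acute-phase apolipoprotein, had a change of 1.44 that did not pass (SE 0.33, limma adjusted p = 0.0566). Cebpa, another C/EBP factor, fell by 1.89 (SE 0.19, limma adjusted p = 0.00802), and Cebpd and Lcn2 did not pass the test (-0.13 and -0.12, limma adjusted p = 0.778 and 0.781). Cebpb is deleted in KO cells and enters the fit at the floor there, so its mean over genotypes says nothing of its response; its signal after stimulation was 1.70-fold the untreated one in WT and 2.58-fold in KI cells, without a test. In all, 16 of 35 tested lists passed camera for stimulation, 0 did with an estimated correlation, and 17 passed limma's fry. The cholesterol synthesis and oxidative stress lists passed camera but not fry (fry adjusted p = 0.108 and 0.147). Housekeeping, eicosanoid synthesis and lysosome genes passed fry but not camera (fry adjusted p = 0.00849, 0.00849 and 0.0157).

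**Figure D1:**
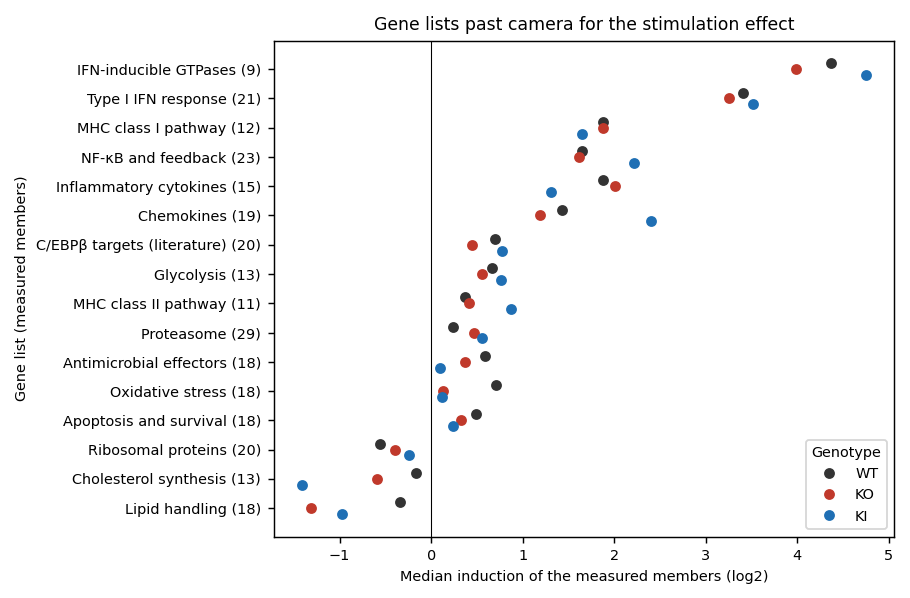
Median log2 induction of the measured members of each gene list that passed camera for stimulation, with 1 point per genotype, each from 2 arrays. The interferon-inducible GTPases lie highest, at 4.37 in WT, 3.99 in KO and 4.75 in KI cells, and the lipid handling list is at -0.35, -1.31 and -0.98.

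The series title asks for gene induction in the 3 genotypes, and the first contrast was KO against WT. Several genes were high in stimulated WT cells and low in stimulated KO cells. Ptges, the inducible prostaglandin E synthase, went from 200 to 2525 in WT and from 60.6 to 242 in KO cells, so that its stimulated signal was 10.4-fold lower in KO. Slc7a2, the arginine transporter that feeds Nos2, reached 4156 in WT and 807 in KO cells from like untreated signals of 251 and 255. Marco, a scavenger receptor for bacteria, reached 2055 and 256, a difference of 8.03-fold, and Il1a, the cytokine interleukin 1α, 3956 and 532, a difference of 7.43-fold. Arg1, the arginine-degrading enzyme, stayed near its untreated signal in WT cells (3949 and 3320) and was 3674 and 388 in KO cells. These differences come from single arrays and have no test. Of the 9344 probe sets, the induction in KO was higher than in WT by at least 1 on the log2 scale for 501 and lower for 671.

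Other genes whose log2 change with stimulation was lower in KO, whether by a smaller rise or a larger decline, included the receptor subunits Il6ra and Csf2rb (differences in log2 change -2.40 and -2.33), the phosphatase Ptpn1 (-2.48), the transporter Abcc1 (-2.35), the adaptor Dab2 (-2.82) and the proliferation genes Tk1 (-4.73), Cks1b (-2.74), Pclaf (-2.54) and Cdk1 (-2.47). Those 4 proliferation genes were higher in untreated KO than in untreated WT cells, Tk1 at 652 against 125. A higher change with stimulation in KO, in some cases a smaller decline, was seen for Cttn, an actin-binding protein (2.82), Hipk2 (2.67), Ramp3 (2.57), Cd72 (2.50), Fgl2, a fibrinogen-like immune regulator (2.34), Rap1gap (2.27), Hhex (2.11), Fscn1, the actin bundler of mature dendritic cells (2.08), Kdr (2.04), Lst1 (1.92), the chemokine Ccl8 (1.85) and Setd4 (1.84). Ptgs2 and Nos2 reached 6938 and 1888 in KO against 5975 and 2766 in WT cells, Il12b 8779 against 4066, Tnf 9610 against 13549, Il1b 3870 against 7088, Il6 1257 against 1908, and Csf3 228 against 508.

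As whole lists, inflammatory cytokines had a lower induction in KO than in WT (median difference -0.60), below all but 0.11% of 10000 random lists matched on expression, or -0.32 and inside the central range (percentile 3.32) with a floor at the 60th percentile. Proteases and clotting genes (-0.84, percentile 0.01), oxidative stress genes (-0.72, percentile 0) and cell cycle genes (-0.74, percentile 0) had lower medians. Mmp14, a membrane matrix protease, reached 4096 in WT and 1325 in KO cells, F10, coagulation factor X, 6517 and 1997, and Sod2 5593 and 1261. The bZIP factor list also lay low (-0.43, percentile 0.5), but inside the central range with other floors, the pseudocount, quantile normalization and median centring, and a floor at the 20th percentile turned it to 0.08 (percentile 66.6). Dendritic cell markers (1.01, percentile 100), type I interferon genes (0.30, percentile 99.6), proteasome genes (0.26, percentile 99.5) and oxidative phosphorylation genes (0.25, percentile 99.5) had a higher induction in KO. For proteasome and oxidative phosphorylation genes the difference from WT lay in untreated cells (-0.23, percentile 1.43, and -0.22, percentile 1.7) more than in stimulated ones (-0.02, percentile 33.6, and 0.07, percentile 90.5), and so did that of cell cycle genes (0.61, percentile 100, against -0.09, percentile 25.1). Of 35 lists, 5 lay below and 4 above the central range of the random lists. For lists of unrelated genes 1.75 would be expected, which is not the chance rate for lists of correlated genes. These percentiles describe the arrays and are not tests.

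The KI line was set beside KO for the genes induced less in KO than in WT. Of 236 probe sets induced at least 4-fold in WT, 47 (34 named genes) were induced less in KO by at least 1.5 on the log2 scale. On a line from KO (0) to WT (1), their median KI position was -0.02 (interquartile range -0.22 to 0.49), 31 lay under 0.25 and 12 at or over 0.5. In 18 of the 34 genes the stimulated KO signal was above WT or less than 2-fold below it, so that by construction their untreated KO signal was above the WT one. Single arrays do not tell a low WT from a high KO signal there. The median KI position of these 18 genes was -0.15 (interquartile range -0.37 to 0.08). For the 16 genes with a stimulated KO signal at least 2-fold below WT it was 0.31 (interquartile range 0.11 to 0.54). This split was made after the values were seen. Hk2, a hexokinase, was at 208 and 3429 in WT and 766 and 2678 in KO cells. Ptges, at 290 in stimulated KI cells, and Slc7a2, at 985, were close to the KO signals, while Marco at 2266, Lmo4 at 5111 and Tnf at 14223 were at or near the WT signals of 2055, 5634 and 13549. Sod2 reached 2874 and Clec4e, a receptor for mycobacterial glycolipid, 484, in KI cells, between KO (1261 and 191) and WT (5593 and 1886). The same construction with the genotypes exchanged gave medians from 0.27 to 0.53, so that selection on single arrays placed the remaining genotype between both ends. Selecting by the stimulated level in place of induction gave 22 probe sets with a median KI position of 0.33, and median centring gave 0.21.

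**Figure D2:**
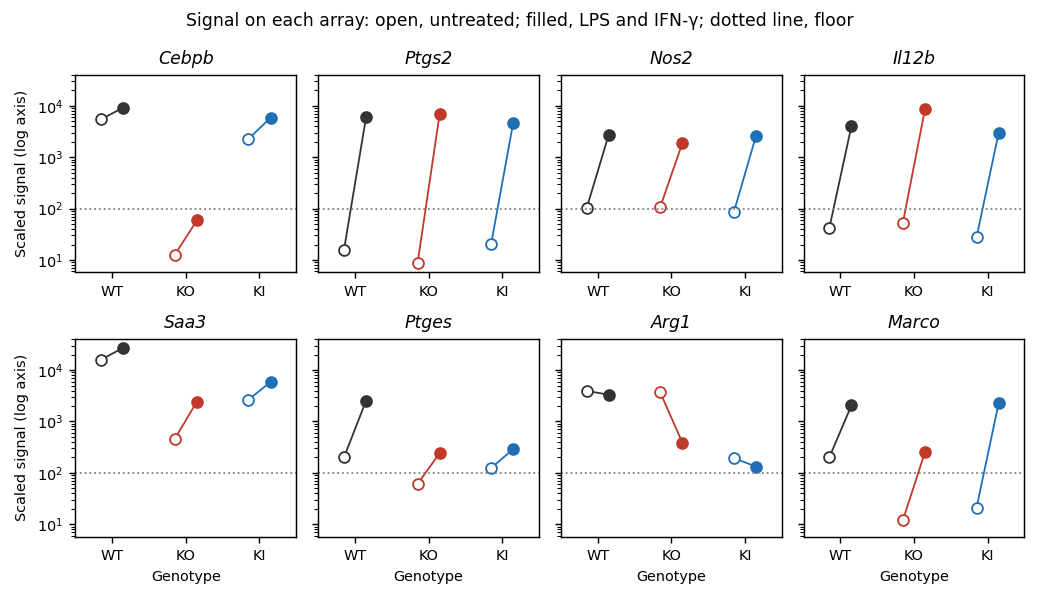
Signals of genes named in the report on the 6 arrays, on a log axis, with open symbols for untreated and filled symbols for stimulated cells, joined within a genotype, and a dotted line at the floor. Each point is 1 array; Cebpb is under the floor in KO cells, and Marco reaches 2266 in stimulated KI cells against 256 in KO.

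**Figure D3:**
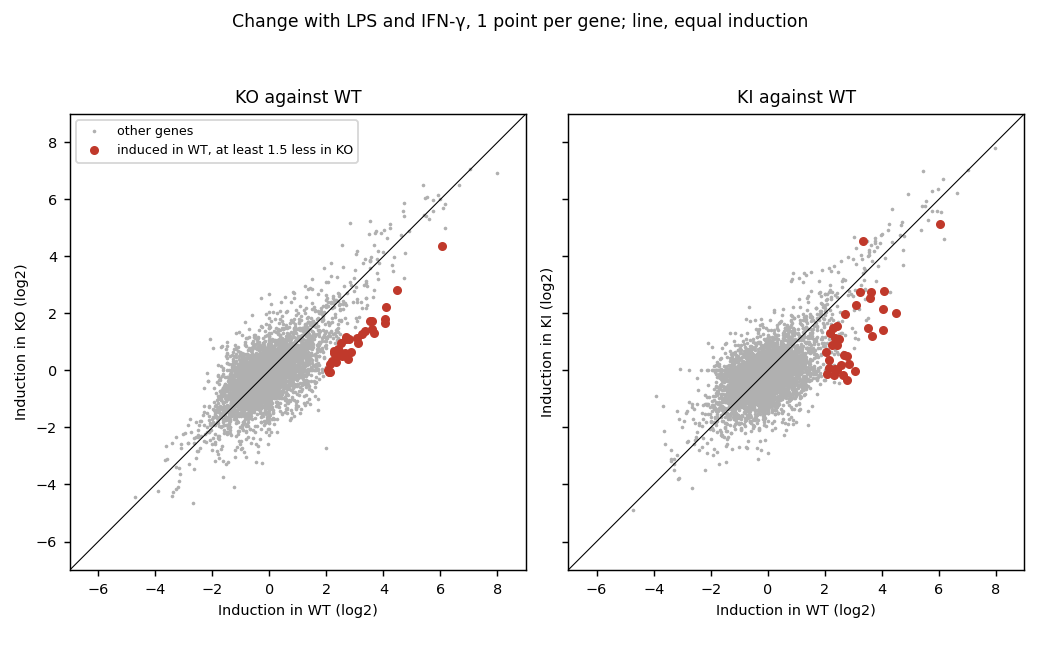
Log2 induction of each named gene in KO (left) and KI (right) cells against that in WT cells, with a line at equal induction and the 34 genes induced at least 1.5 less in KO than in WT in red. Most red genes lie below the line in KI cells as well, and Marco, at 4.53 in KI and 3.35 in WT cells, lies above it.

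The whole response was then compared between genotypes. Pearson's r of the log2 induction across probe sets was 0.757 for KO and KI, 0.707 for WT and KO and 0.633 for WT and KI, where probe sets are not independent and each genotype enters with its own pair of arrays. By size alone, 798 probe sets were higher and 942 lower by at least 1 in WT, 611 and 905 in KO, and 521 and 748 in KI. Median centring turned these splits to 957 and 608, 779 and 676, and 678 and 580, and the median of all probe sets fell by 0.12 on the log2 scale in WT under the main scaling. The difference in induction between KI and WT was at least 1 for 633 probe sets higher and 829 lower, and between KI and KO for 474 and 382. Genes with a larger induction, or a smaller fall, in KI than in WT were led by Ccr2, the monocyte chemokine receptor (3.13), Ltc4s, leukotriene C4 synthase (3.02), Gadd45b (2.86), Scx (2.77), Ccl8 (2.56), Cxcr4 (2.41), Zfp787 (2.37) and Ccl4 (2.35). Mmp9, a gelatinase, had the lowest change with stimulation relative to WT (-3.32), followed by Clgn (-3.12), Ecpas (-3.09), Nt5dc3 (-2.93), Prkcb (-2.92), Dnajc3 and Dusp6 (both -2.83) and Ipo4 (-2.82). Mmp9 was at 1922 in untreated KI cells and 95.3 in untreated WT cells.

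Against KO, the log2 change with stimulation was higher in KI for Ltc4s (3.33), Marco (3.15), Ccr2 (2.74), Arg1 (2.69), Rnase4 (2.67), Birc5 (2.43), Tk1 (2.38) and Ifnar2 (2.35). For Ltc4s, Arg1, Rnase4, Birc5 and Tk1 the change was below 0 in both genotypes and less so in KI, as for Arg1, at 194 and 132 in KI against 3674 and 388 in KO cells. The change was lower in KI for Hipk2 (-3.13), Ifi202b (-3.11), Nadk (-2.70), Prkcb (-2.45), Agap1 (-2.43), Mmp9 (-2.21), Vwf (-2.08) and Gdap10 (-2.00). For lists, NF-κB genes had a larger induction in KI than in both others (median differences 0.66 from WT and 0.75 from KO, percentile 100 in each), and B cell markers differed the same way (0.53, percentile 98.0, and 0.55, percentile 99.5), though inside the central range with quantile normalization, median centring and a floor at the 20th percentile. The NF-κB genes were lower in KI than in KO before stimulation (-0.69, percentile 0) and not after it (0.01, percentile 59.3), and relative to WT they were at -0.26 before (percentile 5.82) and 0.26 after (percentile 99.6). Type I interferon genes (0.49, percentile 99.9) and chemokines (0.44, percentile 99) were above WT. Quantile normalization put the interferon genes inside the central range (0.31, percentile 95.8), and a floor at the 60th percentile the chemokines (0.14, percentile 81.8), as did quantile normalization and the mean of all probe sets of a gene. Inflammatory cytokines (-0.90, percentile 0.04) and cholesterol synthesis genes (-0.86, percentile 0.07) were below WT. After stimulation alone the KI medians relative to WT were 0.42 for interferon genes (percentile 100), 0.03 for chemokines (percentile 74.4), -0.30 for cytokines (percentile 4.19) and 0.00 for cholesterol synthesis genes (percentile 71.1), the latter being 0.83 above WT before it. C/EBPβ literature targets had a median difference from WT of -0.36 in KI (percentile 2.09) and -0.19 in KO (percentile 9.24). With a floor at the 20th percentile the KI value was inside the central range (-0.08, percentile 23.7), as with median centring, and with the mean of all probe sets of a gene the KO value was outside it (-0.62, percentile 0.02), so which genotype lay lower depended on the setting. Dendritic cell markers were induced less in KI than in KO (-0.73). In the KI against WT contrast 5 lists lay below and 6 above the central range, and in the KI against KO contrast 6 and 6.

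Genotypes were then compared within each state. In untreated cells, Saa3 was at 16042 in WT, 460 in KO and 2639 in KI cells, a 34.9-fold difference between WT and KO. Slpi, a secreted inhibitor of leukocyte proteases, was at 2119, 320 and 821. Dcn, a matrix proteoglycan of fibroblasts, was at 1967 in WT, 582 in KO and 337 in KI cells, and Chil3, a chitinase-like protein of alternatively activated macrophages, at 2329, 862 and 123. Besides these and Cebpb, the genes furthest below WT in KO were Aanat (-1.84), Prp2 (-1.68), Clu (-1.49), Hp, haptoglobin (-1.41), Cd302 (-1.31), Pspn (-1.30) and Lst1 (-1.25). Those furthest above were Mnt (2.56), Ubtf (2.53), D17H6S56E-5 and Acin1 (both 2.52), Fmnl1 (2.51), Vps37b (2.50), Man1b1 (2.49), Adam19 and Tk1 (both 2.38), Hmgb2 (2.28), Dctn1 (2.26) and Tgfbi (2.16). In this state 589 probe sets were higher and 402 lower in KO than in WT by at least 1 on the log2 scale, or 664 and 234 with median centring.

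After stimulation, Serpinb2, the plasminogen activator inhibitor type 2, was at 2579 in WT, 158 in KO and 93.3 in KI cells. Slpi was 14.0-fold and Saa3 11.2-fold lower in KO than in WT, Clec4e 9.87-fold, Arg1 8.55-fold, Ghrl 7.37-fold, Cyp1b1 5.45-fold and Cd302 5.32-fold. Cd72, an inhibitory receptor known from B cells, was 10.3-fold higher in KO at 1126 against 110, Hipk2 at least 6.37-fold, Ptger4, a prostaglandin E receptor, 6.00-fold, Car2 4.39-fold, Ccr7, the lymph-node homing receptor, 4.35-fold, Ccnd1 4.25-fold, Kdr 4.12-fold, Mrtfa 3.98-fold, Marcks 3.79-fold, Setd4 3.75-fold, Ccl22, a chemokine of dendritic cells and alternatively activated macrophages, 3.63-fold and Fgl2 3.54-fold. Here 240 probe sets were higher and 303 lower in KO than in WT, or 344 and 226 with median centring. C/EBPβ literature targets lay below WT in stimulated KO (median difference -0.51) and in stimulated KI cells (-0.58), under all 10000 random lists in both contrasts, and mesothelial and fibroblast markers were lower there as well (-0.50, percentile 0.09, and -0.51, percentile 0.23). Inflammatory cytokines (-0.44, percentile 0.08), oxidative stress genes (-0.38, percentile 0) and proteases and clotting genes (-0.61, percentile 0.01) were also lower in stimulated KO cells. In stimulated KI cells oxidative stress genes were at -0.30 (percentile 0.02, and 0.02 to 0.1 over the settings tried); median centring, which shifts whole arrays, gave 0.03 at percentile 0.04.

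KI and WT cells differed at more probe sets before stimulation than after. Mmp9 was at least 19.6-fold, Cdkn1c, a cyclin-dependent kinase inhibitor, 13.1-fold, Prkcb 11.1-fold, Map1s 9.64-fold, Itgax, the integrin CD11c, 8.95-fold and Alas1, the first enzyme of haem synthesis, 8.37-fold higher in untreated KI cells, and Mnt at least 7.68-fold and Mfhas1 at least 7.63-fold. Arg1 was 20.4-fold, Ltc4s 20.3-fold, Chil3 18.9-fold, the haemoglobin gene Hba-a1 14.4-fold, Igkv6-23 13.6-fold, Ifi202b at least 9.53-fold, Cd79b 9.08-fold and Plac8 8.75-fold lower. In untreated cells 759 probe sets were higher and 935 lower in KI than in WT, against 916 and 669 with quantile normalization and 1254 and 441 with median centring, and the median of all probe sets fell by 0.11 under the main scaling. In stimulated cells 177 were higher and 460 lower, against 286 and 284 and against 503 and 226. The genes furthest above WT there were Cd72 (3.25), Cdkn1c (2.56), Ptger4 (2.31), Ccnd1 (2.23), Slc9a3r1 (1.98), Ccl4 (1.97), Map1s (1.96) and Ccnd2 (1.83). Those furthest below were Ifi202b (-5.25), Serpinb2 (-4.72), Arg1 (-4.65), Ghrl (-3.14), Ptges (-3.12), Hba-a1 (-3.10), Hbb-b2 (-2.58) and Chil3 (-2.42), and of these the signals of Ifi202b, Serpinb2, Ghrl and Hbb-b2 in KI were under the floor.

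Between KI and KO, the genes higher in KI besides Cebpb were Cdkn1c (4.29), Mmp9 (3.80), Hipk2 (2.84), Nadk (2.82), Saa3 (2.52), Alas1 (2.43) and Prkcb (2.38) in untreated cells. After stimulation they were Marco (3.15), Gtf2f2 (2.61), Cdkn1c (2.60), Slc27a1, a fatty acid transporter (2.48), Il1a (2.11), Alas1 (1.92) and Pcp2 (1.83). Lower in untreated KI cells were Ltc4s (-4.51), Arg1 (-4.24), Igkv6-23 (-3.40), Ifitm6 (-3.32), Plac8 (-3.19), Hba-a1 (-3.18), Ccr2 (-3.12) and Cd79a (-2.90), and in stimulated KI cells Ifi202b (-5.25), Hba-a1 (-2.57), Ccr7 (-2.50), Cytip (-2.09), Sf3b1 (-1.92), Gdap10 (-1.86), Mypop (-1.67) and Car2 (-1.63). The counts were 265 higher and 501 lower in untreated cells, and 139 and 258 in stimulated cells. Quantile normalization turned them to 338 and 318 and to 193 and 187, and median centring to 461 and 270 and to 268 and 180.

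**Figure D4:**
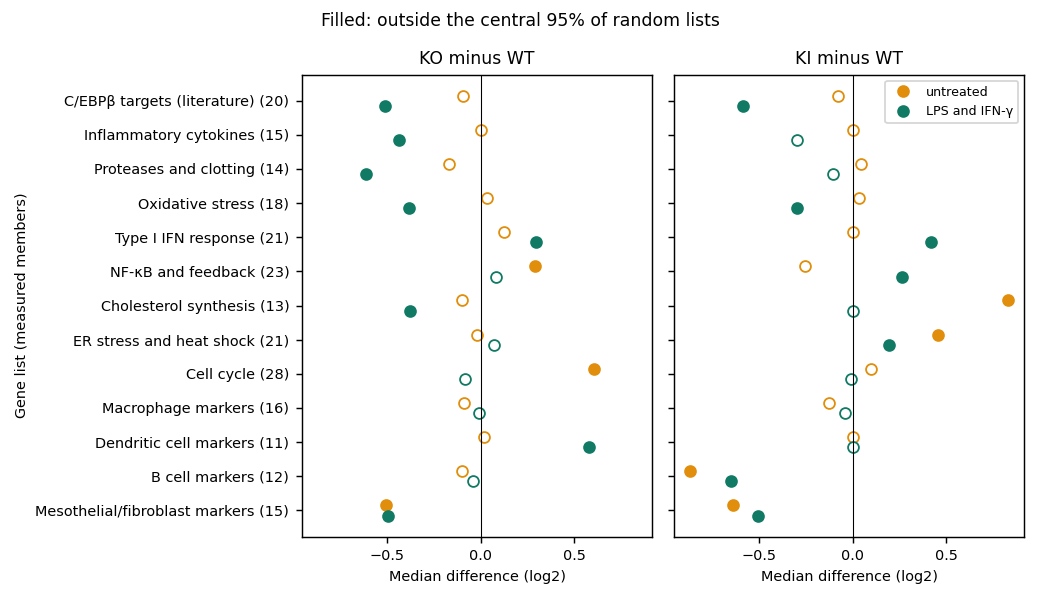
Median log2 difference from WT of selected gene lists in KO (left) and KI (right) cells, untreated and stimulated, with filled symbols for medians outside the central range of 10000 random lists under the main settings. Each median comes from 2 arrays; C/EBPβ literature targets are at -0.51 (KO) and -0.58 (KI) below WT after stimulation.

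Genotype differences shared by both states were tested with stimulation as a block. With limma, 0 of 9344 probe sets passed for KO against WT (946 at an unadjusted p under 0.05, smallest adjusted p = 0.0774) and 0 for KI against KO (703, smallest adjusted p = 0.0900). Cebpb, under the floor on both KO arrays, was therefore not called for KO against WT either. A missing call here does not show a missing difference. For KI against WT 1 passed, a probe set assigned to several genes and therefore unnamed, and 1598 had an unadjusted p under 0.05. The passing probe set was lower in KI (log2 difference -4.38, SE 0.20, limma adjusted p = 0.0299). Its untreated and stimulated signals were 3791 and 2231 in WT, 1541 and 1114 in KO and 160 and 123 in KI cells. Those of Hba-a1 ran in the same order, at 1843 and 1207, 1158 and 835, and 128 and 141. The median SE of a genotype difference was 0.26 on the log2 scale. Without the stimulated WT array, WT enters by its untreated array alone. Such a fit no longer tests a difference shared by both states, and its calls are not given here. Of the lists, mesothelial and fibroblast markers were lower in KO than in WT (median -0.47, camera adjusted p = 0.00141) and type I interferon genes higher (0.28, camera adjusted p = 0.00947), both with adjusted p = 0.902 with an estimated correlation. ER stress and heat shock genes were higher in KI than in WT (0.32, camera adjusted p = 0.00408, adjusted p = 0.944 with an estimated correlation). In KI against KO, cholesterol synthesis (0.41, camera adjusted p = 0.00188), ER stress (0.18, camera adjusted p = 0.004) and lysosome genes (0.16, camera adjusted p = 0.00771) were higher, and B cell markers (-0.68, camera adjusted p = 0.0195) and alternative activation genes (-0.31, camera adjusted p = 0.0216) lower, each with adjusted p = 0.712 with an estimated correlation. None of these passed fry.

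Markers of other cells that a peritoneal exudate could hold were followed in each group. B cell markers were lower in untreated KI cells than in WT (median difference -0.87, percentile 0.37) and KO cells (-1.01, percentile 0). In stimulated KI cells they ran from -0.75 to 0 against WT over the settings tried (percentile 0.07 to 59.7). Cd79a, part of the B cell receptor, was at 1152 in untreated WT, 1130 in KO and 152 in KI cells, and Ighm, the IgM heavy chain, at 3232, 2633 and 789. Mesothelial and fibroblast markers were below WT in stimulated KO (-0.50, percentile 0.09) and KI cells (-0.51, percentile 0.23). In untreated cells they were at -0.51 in KO (percentile 0.5) and -0.64 in KI (percentile 2.36), which moved inside the central range with the mean of all probe sets of a gene (-0.31, percentile 4.88, and -0.15, percentile 48.8) and with a floor at the 60th percentile (-0.23, percentile 7.03, and -0.26, percentile 11.3), and for KI also with quantile normalization, median centring and a floor at the 20th percentile. Resident peritoneal macrophage markers were at -0.40 in untreated KO (percentile 4.75) and -0.72 in untreated KI cells (percentile 2.02) relative to WT, and mast cell markers at -0.66 in untreated KI cells (percentile 0.93). With a floor at the 60th percentile both KI values were inside the central range, at -0.02 (percentile 43.4) and -0.20 (percentile 27.3), and the mast cell value also with quantile normalization. In stimulated KI cells resident macrophage markers ran from -0.54 to 0 against WT over the settings tried (percentile 0.08 to 73.2). Platelet and erythroid markers there ran from -1.41 to -0.11 against KO (percentile 0.04 to 4.58) and from -0.34 to 0 against WT (percentile 21.9 to 63.1). The general macrophage markers were at -0.13 in untreated KI cells (percentile 19.9, and 4.8 to 24.6 over the settings tried); median centring, which shifts whole arrays, gave 0.21 at percentile 20.8. Dendritic cell markers were higher in stimulated KO cells than in WT (0.58, percentile 100), with Ccr7 at 1897 against 436 and Cd83 at 5927 against 2621. With stimulation no cell-type list passed camera, with adjusted p from 0.143 for B cell markers (median -0.30) to 0.903 for mesothelial and fibroblast markers (median -0.07). The medians were -0.32 for macrophage, -0.47 for resident macrophage, -0.09 for neutrophil, -0.35 for mast cell, -0.07 for dendritic cell, -0.11 for platelet and erythroid, and 0.03 for T and NK cell markers. The camera direction was up and the median below 0 for mesothelial, dendritic cell and platelet markers. The eosinophil list had 2 members above the floor and was not tested.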

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

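All tests in this part were chosen only after the result was seen, except the count over splits of the arrays. The genes listed first were picked out because their induction ran in opposite directions, by at least 1 on the log2 scale, in a pair of genotypes. This held for 6 of the 134 genes named and for 28 of all 6767 named genes. Each rests on single arrays, and the difference was not tested.

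Tk1, thymidine kinase of the S phase, went from 125 to 501 in WT and went from 652 to 93.0 in KO cells, a difference in log2 induction of 4.73. Mmp9 differed between WT and KI by 3.32, from a high untreated KI signal of 1922. Dnajc3, an ER co-chaperone, differed between WT and KI by 2.83, with untreated signals of 135 and 649. Il6ra, the interleukin 6 receptor chain, differed between WT and KI by 2.83. Ifnar2, a chain of the type I interferon receptor, differed between KI and KO by 2.35, at 459 and 1079 in KI and 1455 and 670.2 in KO cells. Csf2rb, the shared receptor chain for GM-CSF, differed between WT and KO by 2.33.

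The first pattern is that genes induced less without NF-IL6 had a median position near KO in the LAP knock-in. It held for the 18 of 34 genes whose stimulated KO signal was above WT or less than 2-fold below it, at a median of -0.15. The 16 genes at least 2-fold below WT had a median of 0.31 (interquartile range 0.11 to 0.54). Exchanging the genotypes gave 0.27 to 0.53, but over all selected probe sets and without this split. That range is therefore not a like yardstick for the 16 genes. A weaker stimulation is argued against for interferon genes in KO and KI cells and for NF-κB genes in KI cells. The type I interferon list was induced more than in WT in both, the smaller of both medians being 0.30 and between 0.27 and 0.71 over the settings tried. NF-κB genes differed in induction from WT by medians of 0.51 to 0.74 in KI and -0.03 to 0.15 in KO cells over these settings. Chemokines were not lower as a list, at 0.15 to 0.30 in KO and 0.14 to 0.82 in KI cells. In KO, 7 of 19 chemokines were higher and 4 lower by at least 1. Inflammatory cytokines were induced less, by medians of -0.84 to -0.32 in KO and -0.91 to -0.55 in KI cells. A weaker response of the cytokines and of other genes therefore stays open. So does another stimulation time, since the labels give 12 h for KO and KI cells and none for WT. Noise of the single arrays that chose the genes stays open: by stimulated level the median KI position was 0.33 (interquartile range 0.24 to 0.55), not as close to KO as by induction. WT arrays that stand apart from the others could also give the pattern, and cannot be told apart from it, since among genes induced less in WT the KI position had a median of 0.53 with an interquartile range of 0.12 to 1.04. The genotype itself stays open too and was not tested.

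The second pattern is that KI and WT differed at 1694 probe sets before and 637 after stimulation. This ratio of 2.66 compares with 1.83 for KO and WT and 1.93 for KI and KO, so every pair differed more before stimulation. Untreated arrays correlated at 0.904 for WT and KI, 0.936 for WT and KO and 0.950 for KO and KI. The untreated WT array also had the highest negative-control median, 49.8, so a departure of that array stays open. The 3′ signal of 18S rRNA moved with the pattern, at 167 on the KI and 847 on the WT array before and 207 and 259 after stimulation. A difference in the RNA of these arrays therefore stays open. Signals near background are argued against as the cause, because among bright probe sets the ratio was 3.39, and scaling as the whole cause, because the smaller ratio under quantile normalization and median centring was 2.33. Fewer B cells and other cells in the untreated KI preparation would raise all macrophage transcripts alike. For the higher part of the differences the macrophage list argues against this. Its median was -0.13 (interquartile range -0.44 to 0.12), or 0.21 under median centring, at percentile 20.8 of random lists. A change in the kinds of macrophages present need not show in this list and was not tested. For the lower part a loss of B cells and other cells stays possible, since the B cell list had a median of -0.87 (interquartile range -1.67 to -0.82). With 1 array per group such a loss cannot be told apart from the genotype. The genotype itself stays open here as well, untested.

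The third pattern is Ifi202b, an interferon-inducible gene of the p200 family, which was at 7.10 and 1.0 on the KI arrays and at 3719 and 3726 in stimulated WT and KO cells. A weaker interferon response of KI cells is argued against by the other members of the type I interferon list, which were higher than in WT after stimulation by a median of 0.42. Loss of B cells carrying the transcript is argued against in stimulated cells, since the most reduced of 12 B cell markers was at -1.40 against KO, where Ifi202b was at -5.25. The floor limits how far a marker could fall there. Untreated cells do not decide it: Ifi202b was at 432 in KO and under the floor in KI, and with the floor Cd79a fell further. A strain or donor variant at the locus may explain the Ifi202b signals and stays open. These arrays do not tell whether the KI line or the WT and KO lines would carry it. The lowest difference from KO among 3 measured neighbours, Ifi209, Ifi207 and Ifi204, was 0.0226, and a variant of Ifi202b alone would leave its neighbours as they were. The labels give the strain C57BL/6 for every sample and nothing on backcrossing.

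The stimulation effect was set against other splits of the 6 arrays into groups of 3. The split by stimulation called 1032 probe sets and the highest of the others 897, with 1 of the 10 splits reaching the real count, and 10 splits are too few for a share under 0.05. The 2 splits that called 897 part only the WT arrays while KO and KI keep both arrays on 1 side. They set the change in WT against the changes in KO and KI as the error. They therefore call probe sets that changed in WT and little in KO and KI. Splits that part only the KO or only the KI arrays called 0. With 1 array per group the cause cannot be told and was not tested.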

How the results depend on the processing

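The fit of gene lists without each genotype was chosen after seeing the data, and the other alternatives were planned. The labels number no replicates, so no block by replicate could be fitted; the genotype block of the stimulation fit pairs the untreated and the stimulated array of each genotype. Over 1020 recomputed values of named genes, with both other floors, the pseudocount, median centring and quantile normalization, no stimulation call was lost and no called value changed sign. All 6 arrays bear on the count: without 1 array, 0 to 15 probe sets rose and, at the lowest, 0 fell, with 1 residual degree of freedom. Without WT 0 of the 1032 calls were left, without KO 0 and without KI 13, but 903, 973 and 1024 of them kept their sign with an unadjusted p under 0.05 and 0 changed sign. KO against WT calls ran from 0 to 498 without 1 array and KI against WT calls from 0 to 539, the high values without the stimulated WT array. The cause was not tested. With no filter, probe sets at the floor on all arrays have no variance and shape the prior, and 49 rose and 20 fell, with 4 for KI against WT. Median centring left 372 lower, and a pseudocount in place of the floor gave 989 lower. For genotype effects KO against WT had 1 call with quantile normalization, with a floor at the 20th percentile and with a robust prior, and 9 with the pseudocount. KI against WT had 0 with quantile normalization, with a floor at the 60th percentile, with no trend and with no stimulation block, and 83 with the pseudocount. KI against KO had 2 with the 20th percentile floor and with the robust prior, and 16 with the pseudocount.

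Counts by size depend on the floor, which is where signal over background limits these arrays. With a floor at the 20th percentile, 3099 probe sets moved in WT, 2592 in KO and 2259 in KI. KO and WT then differed at 2265 untreated and 1518 stimulated, KI and WT at 3481 and 1861, and KI and KO at 1927 and 1458. With the 60th percentile, 973 moved in WT and 942 in KO, and the differences were 325 and 217, 693 and 209, and 329 and 120. With the higher array at or above the 75th percentile, 943 moved in WT and 914 in KO, and the differences were 306 and 206, 654 and 193, and 314 and 109. A size rule of 2 left 325, 342 and 276 for WT, KO and KI, and differences of 48 and 44, 178 and 38, and 66 and 21. With the pseudocount KO and WT differed at 568 and 303, KI and WT at 379 stimulated, and KI and KO at 483 and 219.

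The 47 probe sets with a reduced induction in KO became 93 with the 20th and 21 with the 60th percentile floor, 21 with the pseudocount, 84 and 22 with reductions of at least 1 and 2, and 22 by stimulated level. Over these settings the median KI position ran from -0.04 to 0.33. Stimulation lists past camera went from 16 to 0 with an estimated correlation, and each genotype contrast went to 0 with that and to 0 with fry. Otherwise KO against WT had 4 lists with quantile normalization, 4 with median centring, 7 with the 60th percentile floor and 5 with the mean of all probe sets of a gene. KI against WT had 3, 6 and, with the pseudocount, 2. KI against KO had 3 with quantile normalization, 9 with median centring, 3 with the 60th percentile floor and 3 with the mean. Lists outside the random range for induction in KI against WT went from 11 to 7 with quantile normalization. For these changes, beyond fewer or more probe sets passing a floor or size rule, the cause was not tested.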

Other observations

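None of the comparisons in this part carries a test, and those within a state or a single genotype were chosen after seeing the data. Untreated KO cells had higher signals of proliferation genes. The cell cycle list lay above WT there (median difference 0.61, percentile 100 of 10000 random lists), with 9 of 28 measured members higher by at least 1 on the log2 scale. Birc5, a survival and mitosis protein, was at 796 in untreated KO, 229 in WT and 148 in KI cells, Stmn1, a microtubule regulator, at 1822, 568 and 833, and Ccnb2, a mitotic cyclin, at 1580, 536 and 504. After stimulation the list differed from WT by a median of -0.09 in KO cells (percentile 25.1). Ccnd1, a cyclin of the early cycle, ran the other way and was at 1541 in stimulated KO, 1698 in KI and 362 in WT cells.

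Untreated KI cells had higher signals of cholesterol synthesis, chaperone and glycolysis genes. On the same array B cell markers were at -0.87 against WT and -1.01 against KO, and the 3′ signal of 18S rRNA was 167 against 847 and 872. Cholesterol synthesis genes lay above WT by a median of 0.83 (percentile 100) and above KO by 0.69, and were at 0.00 against WT after stimulation. Sqle, squalene epoxidase, was at 2310 in untreated KI cells and 646 in WT, and Idi1 at 1173 and 445. ER stress and heat shock genes lay 0.45 above WT (percentile 99.6), with Hspa5, the ER chaperone BiP, at 9222 in untreated KI, 3252 in KO and 2273 in WT cells, and at 5726 in stimulated WT and 6183 in stimulated KO cells. Glycolysis genes lay 0.41 above WT (percentile 98.0). Lpl, the lipoprotein lipase, was at 18918 in untreated KI and 3776 in WT cells, and this gene was chosen after its values were seen. Interferon-inducible GTPases lay lower in untreated KI cells than in WT (-0.48, percentile 1.32) and KO cells (-0.70, percentile 0.01), but inside the central range with a floor at the 60th percentile (-0.17 and -0.13, percentile 17.6 in each), and against WT also with quantile normalization (-0.23, percentile 23.5) and the pseudocount. NF-κB genes lay lower than in KO (-0.69, percentile 0).

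A few genes stood at least 2 on the log2 scale from both other genotypes in both states. Saa3 and Serpinb2 were higher in WT, Cebpb lower in KO, Cdkn1c higher in KI, and Hba-a1, Ifi202b and 1 probe set without a single gene name lower in KI, with 0 higher in KO and 0 lower in WT. This rule was chosen after the values were seen.

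Further values are given without a test. The probe set for the 3′ end of 18S rRNA was at 259 on the stimulated WT array, 301 on the KO and 207 on the KI array. The ratio of 3′ to 5′ actin signals lay between 1.01 and 1.18 on all 6 arrays. Of the sex-linked genes, Eif2s3y, on the Y chromosome, was at 150 and 82.0 in WT, 456 and 267 in KO and 3.40 and 16.0 in KI cells, and Xist at 127 and 641, 104 and 241, and 473 and 356. The labels give no sex, so a difference in donor sex between the groups stays open.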
